A study of Mus musculus with 8 samples.

How the data were processed

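Total RNA from whole mouse kidney, taken 7 days after ureteral obstruction, was purified with a phenol reagent and spin columns including a DNase step, checked on a Bioanalyzer, amplified to biotin-labelled cRNA and hybridised to Illumina mouse bead arrays, per the labels' protocols. There were 2 groups of 4 animals, control antimiR and anti-miR-214, assigned from the sample titles, with 1 array per animal. The scanner, the export software and their versions were not given in the sources used here.

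The deposited main table held, for each of 45281 probes and 8 arrays, a mean bead intensity on a linear scale, which the file headers call non-normalized. The same deposited table held a detection p-value per probe and array, per the file headers. A second deposited table held processed intensity values with no statement of how they were made. Set against the first table, its values had a rank order equal to that of the same array, the same upper quartile of 147.7 on every array and 29.0% to 29.2% of probes below 0. Values below 0 on a linear scale need a subtraction, and the shared upper quartile points to a normalization between arrays. The column medians were 20.4, 20.4, 20.3 and 20.4 for control replicates 1 to 4 and 20.2, 20.3, 20.2 and 20.3 for anti-miR-214 replicates 1 to 4. The medians differed slightly, and the background and normalization methods behind those values remained unknown, and they served as an alternative only. No column of another series was present (0 columns).

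Intensities were corrected and normalized with limma 3.58.1 in R 4.3.3 by neqc, which fits a normal plus exponential model to the background, here from negative controls inferred from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. The offset presses changes of dim probes toward 0, so their log2 changes understate the differences in RNA. Quantile normalization gives all arrays the same distribution and would hide a shift shared by all genes. A probe was tested when its detection p was under 0.05 on at least 4 of 8 arrays, which kept 18601 probes. Arrays have no read depth. The signal over background stands in its place, with 41.8% to 43.1% of probes detected on control arrays and 37.2% to 39.2% on anti-miR-214 arrays.

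Each probe was fitted with limma's lmFit and eBayes with the group as the only term, and p-values were adjusted by Benjamini-Hochberg over all tested probes, with a threshold of 0.05. Gene names came from the platform annotation supplied with the data, updated through gene numbers with a RefSeq table of assembly GRCm38.p6, which changed 0 symbols. There was 1 symbol for 34885 probes, several for 18, which were left unnamed, and 10378 were not in the table and are unnamed here. Of the tested probes 2560 had no name, 322 of them higher and 379 lower. The array's genome build was not given, so no coordinates are printed. A gene was represented by its probe of highest mean intensity over all 8 arrays. Where a group had no array with a detected signal, the change is given as at least N-fold, the bright group's mean against the dim group's mean of the higher of its own signal and the lowest signal of any detected probe on the same array.

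The genes named were fixed by rule before the data were examined. They were the 12 largest rises and 12 largest falls among genes past the threshold with non-overlapping groups, the 2 members of smallest p in each list, whether they passed or not, and a fixed set of 20 genes of fibrosis, injury and miR-214. Other list members named as examples were chosen after their values were seen. Gene lists, 31 in all, were also fixed beforehand for matrix, fibrosis, injury, immune, vascular, epithelial and neighbouring tissue markers, metabolism, stress and reported miR-214-3p targets. The 29 lists with at least 3 measured members were tested with limma's fry, whose directional p tests whether the members move on balance one way, with Benjamini-Hochberg adjustment over lists. Neither fry p compares a list with other genes. Camera, which does, was run with a preset correlation of 0.01 and with an estimated correlation. With the preset correlation 8 lists passed, all lower. They were the matrix, myofibroblast, TGF-beta, protease, macrophage, endothelial, inflammatory and target lists. With the estimated correlation 0 lists passed and 1 had an unadjusted p under 0.05. Of the lists, 7 had an unadjusted fry p under 0.05 and 15 passed fry's test of change in either direction.

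Array measures were compared with exact permutation tests over all arrangements of the 8 arrays. Pairs of probes of the same gene were compared by fitting their difference on each array with limma. Raw intensities of any 2 arrays correlated at 0.991 or less, and no array held the values of another. The fits were tested on simulated data for this comparison, with 18601 probes of the real means and spreads of which 200 were changed. Of changed probes, 14% were recovered at a log2 change of 0.5, 76% at 1, 90% at 1.5 and 94% at 2, and 4.86% of calls were unchanged probes. In the real data 4761 probes passed, which makes the adjusted threshold less strict there, so these shares can understate recovery. In a simulated shift of the matrix list by -1, the list had a median of -1.06 and an adjusted p of 8.05e-06, and 1 list that shares no member with it was also called. Simulated probes were drawn independently, so this takes no account of genes that vary together and does not test fry under such variation. Figures were drawn with matplotlib 3.10.9.

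Alternatives chosen before the data were examined were no background correction, normexp with an offset of 50, median scaling, the deposited normalized values floored at 10, no detection filter, detection at p under 0.01 on all 8 arrays, trend and robust variance, array weights, the replicate number as a block, the slide as a block, each array left out in turn, other thresholds (an adjusted p under 0.1, a change of at least 1.5-fold), 1 probe per gene, a plain test without a shared variance, camera, and the mean of a gene's probes. Slide 1 alone, both anti-miR-214 arrays 3 and 4 left out, the probe gap as a covariate and the dimmest probe of a gene were added after the data were seen. A planned comparison of genes with and without a miR-214 seed site needs transcript sequences, which were not used here, and it was not run.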

Results

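Gene expression was measured in kidneys of adult male C57/bk mice 7 days after unilateral ureteral obstruction, an operation that blocks urine outflow from 1 kidney and leads to inflammation, tubule loss and scarring. Mice received either an antisense oligonucleotide against the microRNA miR-214 (anti-miR-214) or a control oligonucleotide (control antimiR), with 4 animals in each group and 1 bead array per animal. Antisense oligonucleotides of this kind bind a microRNA and block it from acting on its target messages. Kidneys without obstruction were not analysed here, so every value below compares obstructed kidneys with each other. Each array carried 45281 probes, and 18601 of them (41.1%) passed the detection filter and were tested. The number of arrays limits the precision of each value.

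The median raw intensity was 160 ± 10.4 in control and 161 ± 9.09 in anti-miR-214 kidneys (SD, n = 4, exact permutation test, two-sided p = 0.914). The upper quartile was 307 ± 20.8 in control and 269 ± 20.6 in anti-miR-214 kidneys (SD, n = 4, exact permutation test, two-sided p = 0.0571). Fewer probes were detected after anti-miR-214, 17378 ± 438 against 19178 ± 284 (SD, n = 4), and every anti-miR-214 array lay below every control array (exact permutation test, two-sided p = 0.0286, the smallest p that 4 against 4 arrays allow). The first principal component held 55.8% of the variance and separated the groups. The 4 control arrays lay between -33.8 and -27.1 on it, anti-miR-214 replicates 1 and 2 at 14.5 and 15.4, and replicates 3 and 4 at 46.2 and 49.1. A further measure, called the probe gap here, was the mean difference between the dimmer probes and the brightest probe of the same gene. It was lower on the anti-miR-214 arrays by a mean of -0.0971 on the log2 scale (n = 4 per group, exact permutation test, two-sided p = 0.0286).

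**Figure D1:**
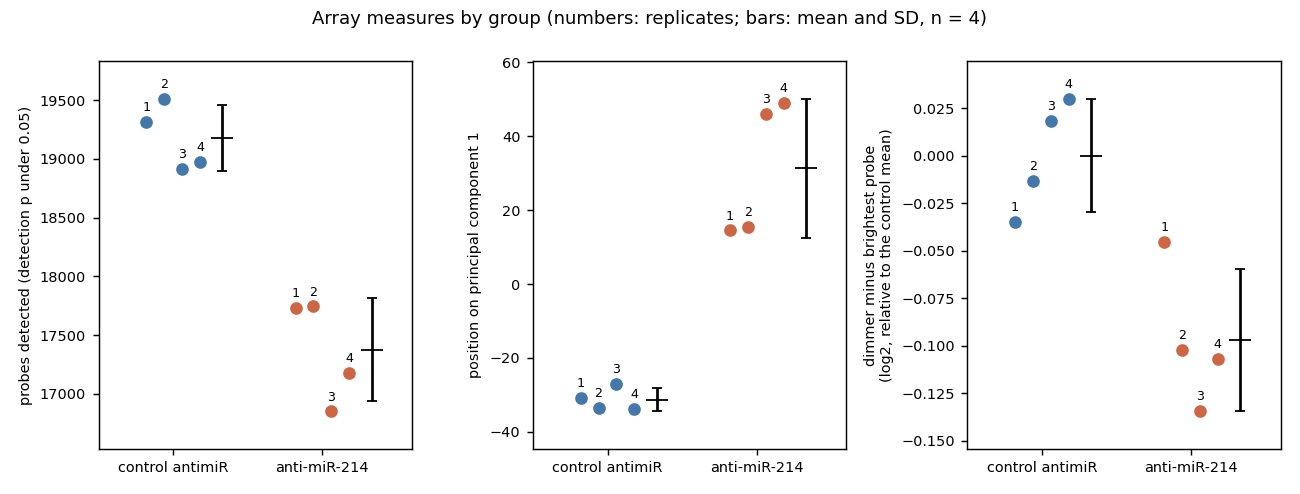
Probes detected (left), position on the first principal component (middle) and mean log2 difference of dimmer minus brightest probes of a gene relative to the control mean (right), with 1 numbered point per array and the mean and SD of each group of 4. The 4 anti-miR-214 arrays had 16852 to 17745 detected probes and the 4 control arrays 18913 to 19513, and no anti-miR-214 array overlapped the control arrays in any of the 3 panels.

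The comparison of anti-miR-214 with control antimiR asks what blocking miR-214 changes in the obstructed kidney. Of 29 genes of the extracellular matrix 16 fell after anti-miR-214 and 13 did not pass. The matrix genes passed as a list (limma fry adjusted p = 0.0442), but not at an estimated correlation in camera (0.929) or with the slide as a block (0.103). With the probe gap as a covariate the adjusted p was 0.435, within a range of 1.87e-11 to 0.929 over 25 alternatives. The podocyte, target and skeletal muscle lists share the value of 0.0442, which was set by the skeletal muscle list with 3 measured genes. Fibronectin (Fn1), a major matrix glycoprotein of scar tissue, fell 5.18-fold on its brightest probe, to a log2 intensity of 8.63 ± 0.79 (SD, n = 4, limma adjusted p = 0.00112), with a smaller log2 change of -1.38 on its other probe, and the fibrillar collagen gene Col1a1 fell 2.41-fold, from 10.99 ± 0.48 to 9.72 ± 0.41 (SD, n = 4, limma adjusted p = 0.0065). The macrophage lysozyme gene Lyz2 fell 5.01-fold on its brightest probe, with log2 changes of -0.57 and -0.43 on its other probes, and the mannose receptor gene Mrc1 fell 2.26-fold. Of 7 podocyte genes 3 rose, among them nephrin (Nphs1, 1.42-fold higher), and 4 did not pass. The podocyte list passed (adjusted p = 0.0442), but not at an estimated correlation (0.929) or with the slide as a block (0.0887), within a range of 0.0179 to 0.929 over 25 alternatives. The cytotoxic lymphocyte gene perforin (Prf1) was 1.88-fold higher, while 12 of 13 T and NK cell genes did not pass. Neither the macrophage list (limma fry adjusted p = 0.18) nor the T and NK cell list (0.498) passed.

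Over all probes, 4761 of 18601 passed the threshold of an adjusted p under 0.05, with 2195 higher and 2566 lower after anti-miR-214. Falls were larger than rises: 639 probes were at least 2-fold lower and 90 at least 2-fold higher. The median log2 change of all tested probes was 0.05. With arrays scaled to a common median in place of quantile normalization, 3455 probes were higher and 2297 lower, and the median of all tested probes was 0.13. The groups did not overlap for 5382 probes (28.9%), against 2.86% that chance gives for 4 against 4. By the brightest probe of each of 10734 named genes, 1323 genes were higher and 1066 lower. With the probe gap as a covariate, a fit added after the data were seen, 3 probes passed. The gap and the group correlated at -0.857 over arrays, so that fit cannot separate them well.

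Both slides held both groups, with replicates 1 to 3 of each group on slide 1 and replicate 4 of each on slide 2. With the slide as a block 5352 probes passed (2612 higher, 2740 lower), and slide 1 alone gave 2556 (1081 higher, 1475 lower). Slide 2 had 1 array of each group, which gives a value and no test. Without anti-miR-214 replicates 3 and 4, the arrays farthest from the controls, 1400 probes passed (429 higher, 971 lower), a comparison added after the data were seen. Without anti-miR-214 replicate 3 alone 2943 passed, and without control replicate 2 alone 3027.

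Of 29 measured members of the extracellular matrix list, which holds collagens, glycoproteins and crosslinking enzymes, 16 fell, 0 rose and 13 did not pass, and the median log2 change was -0.88 (limma fry adjusted p = 0.0442 over 29 lists). The list's call was lost with an estimated correlation in camera, at an adjusted p = 0.929. Adjusted over the list alone, 22 members fell. Lysyl oxidase (Lox), which crosslinks collagen, had a log2 change of -1.77 (SE 0.28, adjusted p = 0.00212), and Col3a1 of -1.16 (SE 0.25, adjusted p = 0.0084). The collagen V genes Col5a1 and Col5a2 and the proteoglycan genes Lum (-1.53) and Dcn (-0.78, other probes -2.11 to -0.39) also fell. Thrombospondin 1 (Thbs1) was not detected on any anti-miR-214 array and was at least 2.26-fold lower (limma adjusted p = 0.000263). Col5a2 was likewise detected on no anti-miR-214 array, and with both genes at their bounds the list's median was -0.84. The basement membrane collagen gene Col4a1, the 1 member above 0, had a log2 change of 0.12 (SE 0.13, adjusted p = 0.52). The list's median was -0.85 on slide 1 and -0.78 on slide 2. In the 10 members with several tested probes the median was -0.81 for the brightest probes and -0.98 for the dimmer ones.

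The matrix list lay close to its threshold. Its adjusted p was 0.103 with the slide as a block and 0.0773 to 0.164 without any 1 of the 4 control arrays or anti-miR-214 replicates 1, 3 or 4, and its range over the 25 alternatives was 1.87e-11 to 0.929. Its median lay between -1.15 and -0.59 over the same alternatives.

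**Figure D2:**
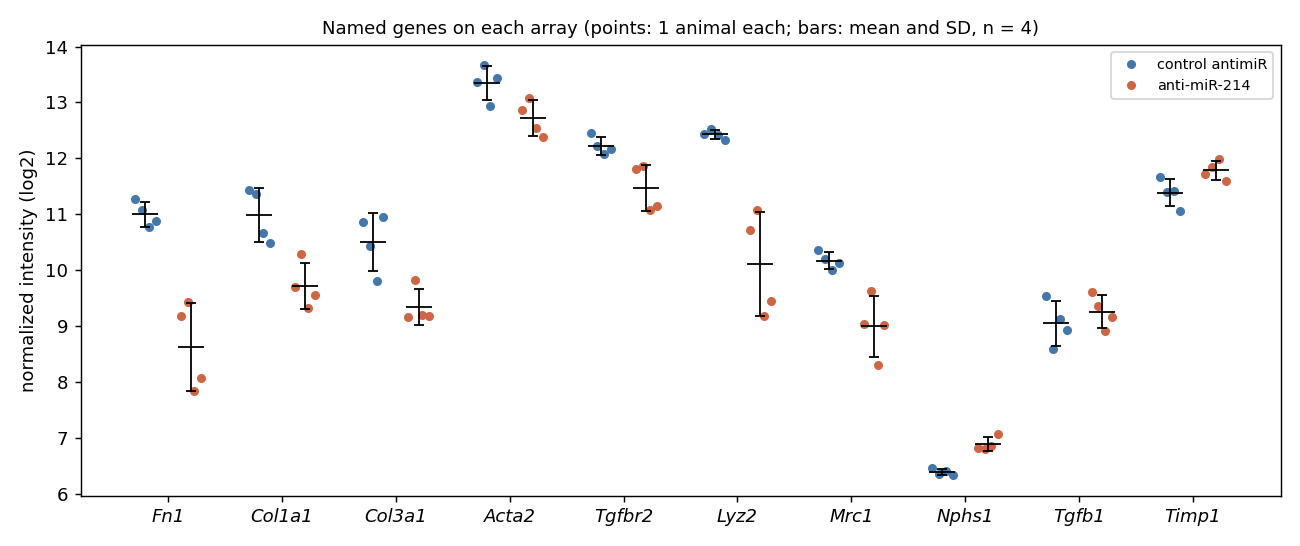
Normalized log2 intensity of 10 named genes in control antimiR (blue) and anti-miR-214 (orange) kidneys, with 1 point per animal and bars for the mean and SD of each group of 4. Fn1, with a mean of 8.63 after anti-miR-214, and Lyz2, with means of 12.43 and 10.10, had no overlap of the groups, while the 2 groups overlapped for Col3a1, Acta2, Tgfb1 and Timp1.

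Related fibrosis lists had fewer members past the threshold, and none of these lists passed the list test. By camera with the preset correlation all of them were lower (adjusted p = 0.00105 to 0.00575), and with the estimated correlation none passed (0.929). Among 17 myofibroblast and mesenchymal genes 5 fell and 0 rose (median -0.36, limma fry adjusted p = 0.18). These were smooth muscle actin (Acta2, -0.63, other probes -1.67 to -0.46), the myosin light chain kinase gene Mylk (-0.70), the myosin light chain gene Myl9 (-0.84), vimentin (Vim, -0.98) and the platelet-derived growth factor receptor gene Pdgfra (-0.74). Among 17 TGF-beta ligands, receptors and targets 6 fell and 0 rose (median -0.36, adjusted p = 0.122), with the receptor gene Tgfbr2 at -0.76 (SE 0.19, adjusted p = 0.0174), Tgfbi at -0.72 and Inhba at -1.87. The ligand gene Tgfb1 had a log2 change of 0.21 (SE 0.21, adjusted p = 0.474) and the TGF-beta target gene Ccn2 of -0.36 (SE 0.21, adjusted p = 0.221), while the other probe of Ccn2 fell by 0.79. Among 19 matrix proteases and inhibitors 7 fell and 0 rose (median -0.56, adjusted p = 0.122), including Adamts1 (-1.16, other probes -0.32 and 0.47, neither past the threshold), the collagenase activator gene Mmp14 (-1.03), Mmp2 (-0.82) and the plasminogen activator gene Plat (-0.85). The protease inhibitor gene Timp1 lay the other way at 0.40 and did not pass (adjusted p = 0.0661). Without anti-miR-214 replicate 2 these lists passed, as did the macrophage, inflammatory and unfolded protein response lists, with an adjusted p = 0.0416 for the TGF-beta list.

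No immune cell list passed the list test. By camera with the preset correlation the macrophage list was lower (adjusted p = 0.00105), and with the estimated correlation it did not pass (0.929). Of 20 macrophage and monocyte genes 5 fell and 0 rose (median -0.45, limma fry adjusted p = 0.18). Lyz2 had a log2 change of -2.32 (other probes -0.57 and -0.43), Mrc1 of -1.18 and the fractalkine receptor gene Cx3cr1 of -0.96, while the pan-macrophage gene Adgre1 did not pass at -0.46 (adjusted p = 0.12), though both its other probes fell (-1.10 and -0.82). In the 7 members with several tested probes the median was -0.46 for the brightest probes and -0.70 for the dimmer ones. Of 13 T and NK cell genes, Prf1 rose by 0.91 (SE 0.15, adjusted p = 0.00231) and 12 did not pass, among them Nkg7 at 0.57 (adjusted p = 0.0545). The list's median was 0.16 (adjusted p = 0.498), with 0.27 on slide 1 and -0.04 on slide 2. Among 29 inflammatory cytokines and chemokines 4 fell and 1 rose (median -0.21, adjusted p = 0.498). The interferon-induced chemokine gene Cxcl10 fell by 1.20, Vcam1 by 0.89 (other probes -0.96 to -0.19) and Ccl6 by 0.95, while Ccl4 rose by 0.44. Ccl2, which recruits monocytes, did not pass at -0.66 (adjusted p = 0.2).

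The interferon response list had 5 members that fell and 1 that rose among 23, with a median of 0.04, a mean of -0.12 and a test direction of lower (limma fry adjusted p = 0.908). The immunoproteasome gene Psmb8 fell by 1.34 on its brightest probe, with the other at -0.14, Gbp3 by 0.74 and the transcription factor gene Irf9 by 0.41, with its other probe at -1.13. Among 12 complement genes C1s1 and Serping1 fell and 10 did not pass (median -0.05, and 0.14 under median scaling). C1s1 was not detected on any anti-miR-214 array and was at least 1.26-fold lower (limma adjusted p = 0.00165). Of 4 B and plasma cell genes Fcrla fell, undetected on all anti-miR-214 arrays and at least 1.11-fold lower (limma adjusted p = 0.0127). The list's median of 0.14 lay opposite to its test direction (adjusted p = 0.94). None of 4 neutrophil genes passed (median 0.02, adjusted p = 0.978), with S100a9 at 0.37 and Mmp9 at -0.29. Of 5 erythroid genes the haemoglobin genes Hbb-bs (-1.64, other probes -1.67 to -0.81) and Hbb-bt (-1.22, other probes -1.60 to -0.94) fell, and the list's median was -1.39 on slide 1 and 0.40 on slide 2 (adjusted p = 0.529 for all arrays).

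Of 7 podocyte genes 3 rose and 4 did not pass, with a median log2 change of 0.43 (limma fry adjusted p = 0.0442). With an estimated correlation in camera the adjusted p = 0.929. Nephrin (Nphs1), a protein of the glomerular filtration slit, rose from a log2 intensity of 6.39 ± 0.06 to 6.89 ± 0.13 (SD, n = 4, limma adjusted p = 0.00969), the cell cycle inhibitor gene Cdkn1c by 0.43 and Clic3 by 0.65. Synaptopodin (Synpo) was at 0.11 and Ptpro at -0.02, and neither passed. The median was 0.35 on slide 1 and 0.55 on slide 2. The list's adjusted p was 0.0887 with the slide as a block and 0.0686 to 0.164 without any 1 of the arrays other than anti-miR-214 replicate 2, within a range of 0.0179 to 0.929 over all 25 alternatives.

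Tubule segment lists did not pass. Among 26 proximal tubule genes the sulfate transporter gene Slc13a1 (0.61) and the transcription factor gene Hnf4a (0.57) rose and 24 did not pass (median 0.04, limma fry adjusted p = 0.92). Adjusted over the list alone, none passed. Among 12 genes of the thick limb and distal convoluted tubule Tmem52b fell by 1.08, and the salt transporter gene Slc12a3 did not pass at 0.38, with other probes at -0.54 to 0.75 (list median -0.04, and 0.12 under median scaling, adjusted p = 0.92). Among 13 collecting duct genes the sodium channel gene Scnn1a rose by 0.88 and Scnn1b did not pass at 0.34 (list median 0.04, adjusted p = 0.92). Of 17 tubular injury genes keratin 7 (Krt7) rose by 0.51, Vcam1 fell by 0.89, and the injury markers Havcr1 (-0.91, adjusted p = 0.0538) and Lcn2 (-0.22, adjusted p = 0.566) did not pass (list median -0.15, adjusted p = 0.738). Of 15 endothelial genes Pecam1 (-1.17, other probes -0.37 and -0.21), Plvap (-1.03) and VE-cadherin (Cdh5, -0.97, other probe -0.27) fell (list median -0.21, adjusted p = 0.498).

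Markers of neighbouring tissues were near the detection limit. The skeletal muscle list, with 3 measured genes, had a median of 0.21 and passed the list test (limma fry adjusted p = 0.0442), though none of its genes passed, with Mylpf at 0.36 (adjusted p = 0.0519) and Tnni2 at 0.21. With an estimated correlation its adjusted p = 0.943, and its median was 0.24 on slide 1 and -0.09 on slide 2. Without anti-miR-214 replicate 3 the adjusted p was 0.0384, without any other 1 array it was 0.056 to 0.164, and over 24 alternatives it ranged from 8.54e-05 to 0.943. Of 4 adipose genes none passed (median -0.26, adjusted p = 0.908), with Fabp4 at -0.64 and Lep at 0.25, and no adrenal gene passed the detection filter.

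**Figure D3:**
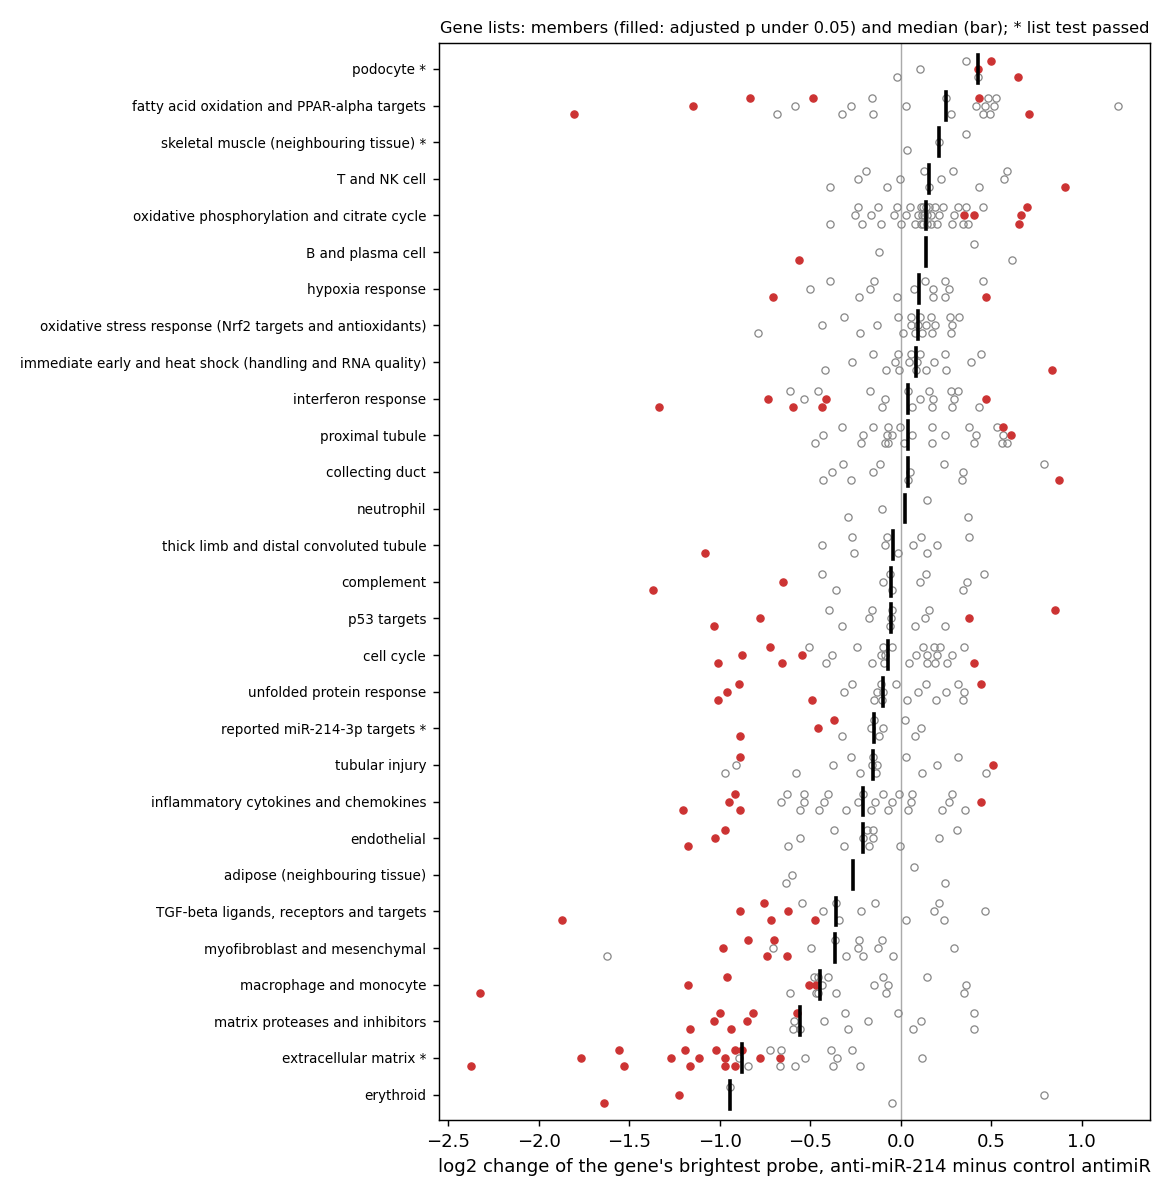
Log2 change (anti-miR-214 minus control antimiR) of the brightest probe of each measured gene in the 29 lists tested, with filled points for genes at an adjusted p under 0.05, black bars for list medians and an asterisk for the 4 lists that passed the list test. The extracellular matrix list had a median of -0.88 with 16 of its 29 genes past the threshold, and the podocyte list a median of 0.43 with 3 of 7.

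Genes of energy metabolism moved in both directions, as named genes did as a whole (1323 higher and 1066 lower of 10734 by the brightest probe). Among 23 genes of fatty acid oxidation and PPAR-alpha targets 2 rose and 4 fell, with a median of 0.25 and a mean of -0.01 (limma fry adjusted p = 0.94, and 0.00251 for change in either direction). The test of change in either direction was passed by 15 of 29 lists and does not compare a list with other genes. Adjusted over the list alone, 7 rose and 5 fell. The acyl-CoA dehydrogenase gene Acadl fell by 1.80 on its brightest probe, while its other probes lay at 0.45 and 0.55, the reverse direction. The pyruvate dehydrogenase kinase gene Pdk4 fell by 1.15, and the carnitine acyltransferase genes Crat (0.71) and Cpt1a (0.43) rose. Among 42 genes of oxidative phosphorylation and the citrate cycle 5 rose and 0 fell (median 0.14, adjusted p = 0.498). These were Ogdh (0.67), Ndufb10 (0.70), Uqcrc1 (0.65), Ndufs8 (0.40) and Ndufa2 (0.35). Adjusted over that list alone, 2 rose and 0 fell.

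Among 28 cell cycle genes 5 fell and 1 rose (median -0.07, limma fry adjusted p = 0.908). The replication genes Pcna (-0.72), Mcm4 (-0.55) and Mcm3 (-0.88) and the topoisomerase gene Top2a (-1.01, other probes -0.57 and 0.35) fell. Among 21 genes of the unfolded protein response 4 fell and 1 rose (adjusted p = 0.175, and 8.45e-05 for change in either direction, a test that 15 of 29 lists passed). The endoplasmic reticulum folding genes Pdia3 (-0.96), Calr (-1.01), Pdia4 (-0.49) and Dnajb9 (-0.90, other probe -0.11) fell and the stress transcription factor gene Ddit3 (0.44) rose. The list's median was -0.10, and 0.16 under median scaling. Among 15 p53 targets Pmaip1 (-1.03) and Trp53inp1 (-0.78, other probe -0.10) fell, and Tnfrsf10b (0.86, other probe 0.02) and Aen (0.38) rose (median -0.05, adjusted p = 0.59). Among 16 hypoxia response genes the glycolytic gene Aldoa rose by 0.47 and the oxygen sensor gene Egln1 fell by 0.71 (median 0.10, adjusted p = 0.498).

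None of 21 oxidative stress genes passed (median 0.10, limma fry adjusted p = 0.738). Its members of smallest p were Srxn1 at 0.32, whose other probes lay between -0.88 and -0.16, and Sod3 at -0.31. Among 19 immediate early and heat shock genes, fixed as a sign of handling and RNA quality, the heat shock gene Hsph1 rose by 0.83 and Klf2 did not pass at -0.42 (median 0.08, adjusted p = 0.59). For the hypoxia, oxidative stress, collecting duct, fatty acid oxidation and neutrophil lists, camera placed the list lower than other genes while the median and the fry direction were above 0.

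Of 11 measured genes reported as direct miR-214-3p targets 3 fell, 0 rose and 8 did not pass, with a median log2 change of -0.15 (limma fry adjusted p = 0.0442). With an estimated correlation in camera the list's adjusted p = 0.929, and its median was -0.24 on slide 1, -0.11 on slide 2 and 0.03 under median scaling. The calcium/calmodulin kinase gene Camk2d fell by 0.89 (SE 0.15, adjusted p = 0.00335), the histone methyltransferase gene Ezh2 by 0.46 and beta-catenin (Ctnnb1) by 0.37. The other probes of Camk2d lay between -0.38 and 0.35 and none passed, and those of Ctnnb1 lay between -0.75 and 0.36. The RNA-binding protein gene Qk was at 0.02 (SE 0.12, adjusted p = 0.903). The members Atf4 (other probe -1.24) and Xbp1, which did not pass, also stand in the unfolded protein response list. The list's adjusted p was 0.0669 with the slide as a block and 0.0517 to 0.164 without any 1 of the arrays other than anti-miR-214 replicate 2, within 0.0288 to 0.929 over 25 alternatives. The transcript Dnm3os, from which miR-214 is processed, had a log2 change of 0.10 (SE 0.21, adjusted p = 0.753), with another probe at -0.40. No probe of the mature microRNA was measured, and the probes of Twist1 and Ppara did not pass the detection filter.

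Among genes with non-overlapping groups, the 12 largest rises ran from 1.79 for Prrc2c to 1.18 for Heatr3 on the log2 scale. The rise of Prrc2c was seen on a further probe (1.72), and another lay at -0.43. The rises included the amino acid transporter family gene Slc6a18 (1.33, SE 0.22), the chloride channel subunit gene Bsnd (1.23, SE 0.31) and the myo-inositol transporter gene Slc5a3, undetected on all control arrays and at least 1.92-fold higher (limma adjusted p = 0.00991). The others were 2900060B14Rik (1.58), Afap1 (1.36, other probe 0.54), Hykk (1.33), Pgam2 (1.24), the heme-responsive repressor gene Bach1 (1.23), Ehd1 (1.21) and the lysosomal protease gene Ctsd (1.18).

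The 12 largest falls ran from -2.69 for the purine synthesis gene Adss (6.45-fold lower, SE 0.42) to -1.99 for the laminin gene Lama2. Besides Fn1 and Lyz2 they were the endoplasmic reticulum gene Rtn4 (-2.43), Rnf13 (-2.41), the splicing factor genes Hnrnpa2b1 (-2.26) and Hnrnpf (-2.19), the signal recognition particle gene Srp54a (-2.20), the phosphatase gene Ppp1cb (-2.18), Rab6a (-2.10) and the histone chaperone gene Rbbp7 (-2.09). Other probes of Hnrnpa2b1 lay between -0.05 and 0.22 and those of Rab6a between -1.71 and 0.25. For Ppp1cb, Rbbp7, Rtn4 and Fn1 every tested probe fell. Several of these probes were near background after anti-miR-214, which limits the sizes and ranks given. Of 4 anti-miR-214 arrays, Rnf13 and Lama2 were detected on 1, Adss, Rtn4 and Srp54a on 2, and Hnrnpf and Rab6a on 3.

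Probes of the same gene often gave different changes. In 5307 pairs of a dimmer probe with the brightest probe of its gene, over 3769 genes, 1492 pairs (28.1%) differed past the threshold, with the dimmer probe lower in 1027 and higher in 465. In 124 genes, probes passed the threshold in both directions. As examples chosen after their values were seen, the chaperone gene Hspa8 had log2 changes of -2.43, 0.28 and 0.06, and the sugar kinase gene Nagk had changes of -2.81, -2.98, -2.26 and 0.01.

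**Figure D4:**
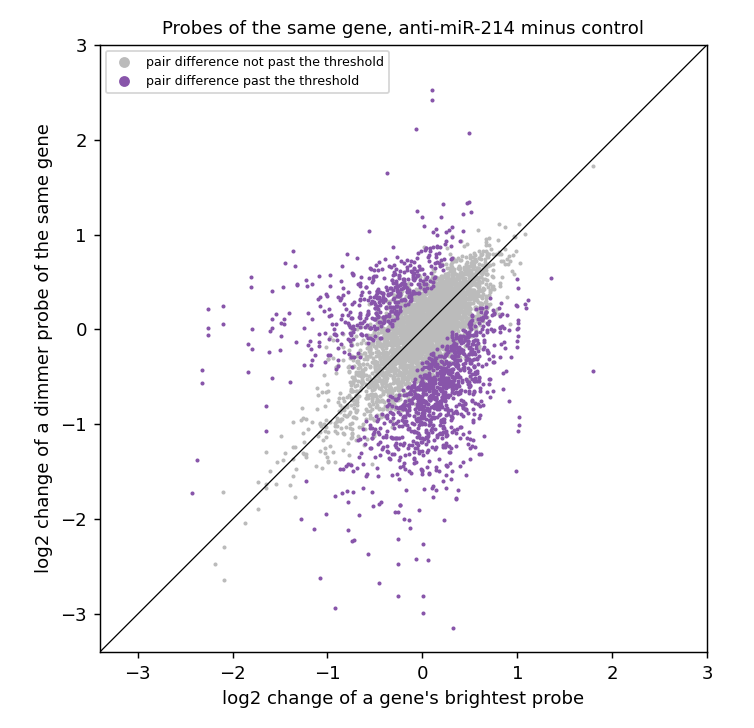
Log2 change (anti-miR-214 minus control antimiR) of a dimmer probe (vertical) against that of the brightest probe of the same gene (horizontal), with 1 point per pair, purple where the pair's difference passed an adjusted p under 0.05 and a diagonal line where both are equal. Of 5307 pairs 1492 are purple, 1027 of them below the line.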

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

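The 4 values of each group were searched for an array whose distance to the nearest of the others took a larger part of the group's range than the limit of Dixon's test for 4 values, for all named genes, list means and array measures. Of 250 groups 11 (4.4%) had such an array, and chance alone gives about 1 in 20. No explanation was tested for these values.

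In the anti-miR-214 group replicate 2 lay above the others for several fibrosis results. For Col3a1 it was at a log2 intensity of 9.83 with the lowest of the others at 9.17 (distance 0.956 of the range), and for Ccn2 it was at 12.81 with the others at 11.96 to 12.03 (distance 0.918). Its mean over the TGF-beta list, relative to the control mean, was -0.14 with the others at -0.47 to -0.41 (distance 0.838). Without this array the log2 change of Ccn2 was -0.56 with a limma adjusted p of 0.0302, past the threshold that it missed with all arrays.

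Replicate 4 of the anti-miR-214 group stood apart for 2 dim muscle genes and for Qk. Mylpf was at 6.44 with the others at 6.08 to 6.13 (distance 0.847), Tnni2 at 5.78 with the others at 6.30 to 6.33 (distance 0.943), and Qk at 7.41 with the others at 7.61 to 7.64 (distance 0.87). Replicate 3 had the adipose hormone gene Lep at 6.88 with the others at 6.35 to 6.43 (distance 0.844).

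Among the controls, replicate 4 was low for genes that rose after anti-miR-214. Bach1 was at 7.17 with the others at 8.07 to 8.20 (distance 0.87) and Ehd1 at 7.00 with the others at 8.19 to 8.41 (distance 0.844). Without this array the log2 change of Bach1 was 0.99 and the log2 change of Ehd1 was 0.89, and both still passed. Control replicate 1 had the endothelial gene Plvap at 11.82 with the others at 11.38 to 11.45 (distance 0.856), and the mean of the adipose list in control replicate 2 was 0.65 with the others at -0.29 to -0.17 (distance 0.879).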

How the results depend on the processing

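Leaving out both anti-miR-214 arrays 3 and 4, the probe gap covariate, slide 1 alone and the dimmest probe were chosen after the data were seen. A change of sign was counted as a reversal only where the result passed the threshold in the main fit or in the alternative. Among named genes, 1633 of 1931 values under the alternatives stayed on their side of the threshold without such a reversal. A further 263 kept the direction and no longer passed, 35 passed newly and 0 reversed. Of 721 list medians 629 stayed in this sense and 3 reversed. The target list's median went to 0.0289 under median scaling and to 0.0232 with the dimmest probe, and the hypoxia list's to -0.0356 with the dimmest probe. These are signs of the median only for the target list, which the list test still called lower in each of these alternatives (limma fry adjusted p = 0.0288 and 0.0363). Sign changes of lists that passed in neither were not counted, such as the complement list from -0.05 to 0.14 under median scaling. Where no cause follows from how an alternative was built, such as fewer arrays or probes or another threshold, the cause was not tested. Of the 4761 probes past the threshold, 4249 stayed past it in the same direction in the deposited normalized values, 4250 without background correction and 4275 under median scaling. Probes higher numbered 3455 under median scaling, and probes lower 1637 with the strict detection filter. Without anti-miR-214 arrays 3 and 4 there were 1400 probes (429 higher, 971 lower), of which 1348 were among the 4761. Slide 1 alone gave 2556 (1081 higher, 1475 lower). An adjusted p under 0.1 gave 3439 higher, a change of at least 1.5-fold gave 2689 (892 higher), and 1 probe per gene, adjusted over those probes alone, gave 2233 (1236 higher, 997 lower). The plain test gave 3550 higher at an unadjusted p under 0.05 and 1697 lower after Benjamini-Hochberg. With the probe gap as a covariate limma gave 0 higher and 3 lower probes (3 in all), with 2103 at an unadjusted p under 0.05, as the gap and the group correlated at -0.857 over arrays. The median absolute log2 change of the 4761 probes then went from 0.62 to 0.47 and their median SE from 0.15 to 0.27, with 174 in the opposite direction. Leaving out 1 array gave 2943 to 4815 probes, 1214 to 2195 higher and 1729 to 2629 lower, with the lowest counts without anti-miR-214 replicate 3. The list calls were less stable. They fell to 0 higher and 0 lower (0 lists) by limma fry without background correction, with normexp offset 50, in the deposited normalized values, without a detection filter, with the strict detection filter, with the slide as a block, with the probe gap covariate and on slide 1 alone, and by camera with an estimated correlation. The lists at an unadjusted p under 0.05 then numbered 8, 8, 7, 6, 6, 6, 1, 6 and 1. With the probe gap covariate the list medians were -1.15 for the extracellular matrix list (-0.88 without it), 0.40 for the podocyte list (0.43) and -0.15 for the target list (-0.15). Median scaling gave 1 list lower, array weights 0 higher and 1 lower (1 list), both arrays 3 and 4 left out 1 higher and 1 lower (2 lists), camera with the preset correlation 0 higher and 8 lower (8 lists), and the dimmest probe 5 lower (7 lists). Leaving out 1 array gave 0 to 9 lists, 0 to 1 higher and 0 to 8 lower, with the highest counts without anti-miR-214 replicate 2. With the replicate block 4598 probes (2121 higher, 2477 lower) and 2 lists passed (0 higher, 2 lower). The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at 0.015, 0.0631, 0.0508 and 0.204, and control 1 correlated best with anti-miR-214 replicate 2 (0.386). Signal over background limits the dim genes, and the skeletal muscle list had no value under the strict detection filter. The seed-site comparison and its site definitions were not run, since transcript sequences were not used here.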

Other observations

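The tests of the slide and position, of the matrix list's probes, of the tubule share and of the target list's probes were chosen after the results were seen, as were the genes with every probe past the threshold. In 171 genes every one of several tested probes fell after anti-miR-214, and in 103 every one rose. The falls with the largest smallest change were the phosphatase gene Ppp1cb (-2.18, SE 0.19, here and below on the brightest probe), the histone chaperone gene Rbbp7 (-2.09, SE 0.22), the glucuronosyltransferase gene Ugt1a7c (-1.87, SE 0.36), Rtn4 (-2.43) and the translation elongation factor gene Eef2 (-1.73, SE 0.32). Further falls were those of Sumo3 (-1.61), Klhl9 (-1.39), Rnf114 (-1.34), Rnf4 (-1.44) and Usp8 (-1.25). The tumour necrosis factor receptor gene Tnfrsf1a fell on 3 probes (-1.25, SE 0.24). Rises were smaller. Ranked by the smallest change among a gene's probes, they were led by the protease inhibitor gene Serpina1a (0.98, SE 0.22) and the membrane protein gene Palm (0.97, SE 0.14). They included Cfap69 (0.87) and Rsph9 (0.68), the anion exchanger gene Slc4a3 (0.83), the lysosomal protease gene Ctsz (0.68) and Ndufb10 (0.70).

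Probes of the same gene changed by different amounts in 1492 of 5307 pairs. Of 35 splits of the 8 arrays 1 gave as many, the real one, with 0 pairs in the highest other. That argues against chance, though 1 of 35 is the smallest share this test can give. Background correction is argued against, since 84.0% of these pairs were still called in the same direction without it, and so are the slide and position, since pair differences on slide 1 and on slide 2, where the groups lay in the reverse order, correlated at 0.791 over pairs. A loss of signal along transcripts, from RNA integrity or amplification, stays open. The gap of dimmer minus brightest probes was lower on all 4 anti-miR-214 arrays, by a mean of -0.0971. It cannot decide the question, since it is the mean of the same pair differences and probe positions were not used. With the gap as a covariate 3 of 4761 calls were left, as the median absolute log2 change went from 0.62 to 0.47 and the median SE from 0.15 to 0.27, with 4587 probes in the same direction, 1228 of them changed more than without it and the others less, and 174 in the opposite direction, so calls were lost both to smaller changes and to wider errors, and how much of the changes the gap accounts for stays open. A change in transcript forms after anti-miR-214 stays open and untested, since probe positions along transcripts were not used here.

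The extracellular matrix list was lower, with 16 of 29 members past the threshold and a median of -0.88, a call lost at an estimated correlation (adjusted p = 0.929) and without any 1 array other than anti-miR-214 replicate 2 (0.0773 to 0.164). Chance is argued against for the count over all probes, though this does not test the list itself. Of 35 splits 1, the real one, gave as many probes (4761, highest other 1), and 1 gave as many lists (4, highest other 1). The smallest share such a count of splits can give is 1 of 35. For the lists it cannot decide, since splits were counted in the main fit only and no list passed in alternatives such as no background correction. A signal loss common to genes of like brightness, probe number and gene length is argued against by the median, at percentile 0 of 10000 matched random lists. Their 2.5th percentile was -0.10. Random members were drawn independently, so the percentile takes no account of genes that vary together. Probe position along transcripts was not matched, so a loss by position stays open. A larger share of tubule cells is argued against as the whole cause by the podocyte list, which would have fallen. Its median was 0.43 (0.22 to 0.50 over 25 alternatives). The argument is weak, since the list has 7 measured genes, of which 4 did not pass. Its call held in 5 of the 25 alternatives and in 1 of 8 fits with 1 array left out. It was lost at an estimated correlation in camera (adjusted p = 0.929). As part of the cause a larger tubule share stays open. The medians of the macrophage (-0.45), myofibroblast (-0.36), erythroid (-0.94, but 0.40 on slide 2) and endothelial (-0.21) lists were lower too. The tubule lists, which would have risen, had medians of 0.04 (proximal), -0.04 (thick limb and distal) and 0.04 (collecting duct). Under median scaling these were 0.32, 0.12 and 0.03. A loss of signal along transcripts cannot be told apart in the 10 members with several probes, whose brightest probes had a median of -0.81 with 5 of 10 past the threshold, which leaves their number too small to decide. Lower matrix expression after anti-miR-214 could be the biological part of this pattern, a hypothesis left open because the probe gap moved with the group: with the gap as a covariate the median was -1.15, no smaller than without it, but the members' median SE went from 0.25 to 0.50 and the call ended (adjusted p = 0.435).

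The reported miR-214-3p targets passed the list test with a median of -0.15, a call lost at an estimated correlation (adjusted p = 0.929), and the median was 0.03 under median scaling. Among 10000 random lists matched on brightness, probe number and gene length the median of -0.15 lay at percentile 6.3, so a chance choice of genes could give it. A loss of signal along transcripts cannot be told apart for this list, since its dimmer probes minus its brightest had a mean difference of -0.00466 (SE 0.22 over 7 genes), too wide to decide. Release from miR-214 would raise direct targets, and 0 of 11 measured members rose past the threshold. Small rises could be missed, since in simulated data 14% of changed probes were recovered at a log2 change of 0.5. That simulation changed 200 of 18601 probes, against 4761 past the threshold in the real data, which made its adjusted threshold stricter. The 14% can thus understate recovery here, where the list member Ezh2 passed at -0.46 (limma adjusted p = 0.0375). The mature microRNA was not measured, so release itself was not tested.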
